A study of Mus musculus with 8 samples.

How the data were processed

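Messenger RNA of 8 mouse livers was measured by RNA sequencing, 5 from wild-type and 3 from males that the genotype label calls hemizygotes for Midn and the titles Het, all of 1 strain on the same diet. Per the labels, livers were kept in RNAlater, RNA was taken up with a miniprep kit and treated with DNase, and libraries were made with the KAPA mRNA HyperPrep kit (Roche). Per the submitters' processing notes, bcl2fastq 2.18.0.12, STAR and HTSeq were used with the mouse genome build mm10. The versions of STAR and HTSeq, the gene annotation, the counting mode and the use of strand are not given in the sources used here. Overlapping and antisense genes therefore cannot be separated, and members of families with near-identical copies, such as Mup and Cyp genes, are uncertain.

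The authors deposited raw counts per gene, whole numbers with a different total in each library, for 25078 genes. They also deposited RPKM values and the total exon length of each gene. Each deposited RPKM value equalled the count divided by exon length and by 1 constant per library. That constant corresponds to an effective library total of 0.888 to 1.25 times the count total, and how it was made is not given in the sources used here. Unused sample columns numbered 0. The leading numbers of the sample titles have a gap between het-labelled libraries 2 and 3, and the sources used here do not say why. In 4 entries 2 gene symbols occurred more than once, as date-like names, and were made unique. Total counts ran from 17508221 to 24916239 per library. Groups were taken from the genotype label and replicates were numbered in accession order. The numbers do not pair libraries across genotypes. The titles carry a different animal-like number for each sample, but the labels do not describe litters or batches, so p-values measure the spread between these samples. Counts of replicate pairs were compared by chi-square over genes with a summed count of at least 20. The lowest chi-square per degree of freedom was 22.9 among wild-type pairs and 36.0 among heterozygous pairs, so each library was counted as 1 replicate.

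Genes were kept with edgeR's filterByExpr (minimum count 10, minimum total 15), which left 14438; 5912 genes had no count in any library. Counts were scaled by TMM, whose factors ran from 0.852 to 1.27, and tested with edgeR's quasi-likelihood test with robust estimation, two-sided, with Benjamini-Hochberg adjustment at 0.05. CPM values are counts scaled by TMM to a common library total. Gene lists, 42 with 785 symbols in all, were fixed in advance. Of the symbols, 10 were not in the deposited tables and 47 stood in more than 1 list. The 40 lists with at least 4 tested members were tested with limma's camera with a preset correlation of 0.01 on log2 CPM with voom weights. They were tested again with an estimated correlation and with fry. A list score is the mean over members of log2 CPM (prior count 2) after subtracting each gene's mean over the 8 libraries. The 95% interval of a score difference against wild-type libraries 1 and 3 takes the spread pooled within both groups and assumes normal errors. Principal components used log2 CPM. Scores and single measures were compared by two-sided exact permutation tests over the 56 assignments of 3 among 8 libraries. Intervals are at 95%. Enrichment of DESeq2 calls in lists used Fisher's exact test, one-sided for more calls, against all genes DESeq2 gave an adjusted p. Higher and lower calls were tested apart, and their p-values were adjusted together over the lists. Fisher's test takes genes as independent of each other.

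Genes named are Midn, the genes with the smallest p in edgeR in each direction (5 per direction, since 0 passed), up to 4 members with the smallest p of each list, and 22 genes fixed in advance. Predicted genes and pseudogenes were to be passed over, which applied to 0. Alternatives were RLE scaling, library size alone, DESeq2, limma-voom, no filter, a mean of at least 1 CPM, no robust estimation, limma on log2 RPKM with pseudocounts of 0.1 and 1, 1 surrogate variable from sva, thresholds of 0.01 and 0.10 and a 1.5-fold minimum, camera on ranks, and each library left out in turn. Chosen after seeing the data were the fits without Rn45s and Rpph1, without wild-type libraries 1 and 3, and without wild-type libraries 2, 4 and 5. The tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, sva 3.50.0, Python 3.11.15 and matplotlib 3.10.9.

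The procedure was tested on simulated data with the real means and library sizes of 14438 genes, of which 200 were changed, 50 at each fold. edgeR called 2 of 50 genes at 1.5-fold, 16 at 2-fold, 36 at 3-fold and 44 at 4-fold, with 0 in the wrong direction and 6 false calls among 14218 unchanged genes. DESeq2 called 5, 33, 45 and 48, with 50 false calls. A list of 20 genes shifted by 0.5 gave a camera adjusted p of 2.94e-10, and 1 of 20 unchanged lists was called. Correlation between genes was not simulated.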

Results

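Liver RNA was sequenced from 8 male C57/BL6 mice that had eaten a Western-style diet rich in cholesterol, fat and fructose for 25 weeks, a regimen that brings about fatty liver disease. By the labels, 5 livers were wild type and 3 came from mice with 1 intact copy of Midn. The genotype label calls these hemizygotes and the titles Het, and they are here called het-labelled. Midn encodes midnolin, a nuclear protein known for carrying short-lived transcription factors to the proteasome without ubiquitin. The submitters' design text asks what midnolin does in fatty liver disease, and gives the early death of most homozygous embryos as the reason for studying heterozygotes. Counts assigned to genes summed to between 18687680 and 21064473 per wild-type library, and to 24916239, 17508221 and 24645260 in het-labelled libraries 1, 2 and 3. Total counts differed between the groups with p = 0.214 in a two-sided exact permutation test, for which the smallest possible p was 0.0357. Between 16698 and 17607 genes had at least 1 count in a library.

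The share of Rpph1, the RNA component of ribonuclease P, which carries no poly(A) tail, parted the wild-type libraries. It was 0.899, 0.673 and 1.06% of counts in wild-type libraries 2, 4 and 5, against 0.331 and 0.304% in wild-type libraries 1 and 3. The 3 het-labelled libraries had 0.229, 0.399 and 0.288%. The libraries with a high share were thus all wild type, and the 5 with a low share held 2 wild-type and 3 het-labelled livers. Genotype did not separate the libraries on the first principal component (48.9% of variance), where wild-type libraries ran from −71.8 to 30.6 and het-labelled ones from −10.5 to 51.9. Wild-type libraries 1, 2 and 3 (−43.15, −27.6 and −71.8) and het-labelled library 2 lay below 0 there. Wild-type libraries 4 and 5 (30.6 and 27.9) and het-labelled libraries 1 and 3 (42.7 and 51.9) lay above 0. On the second component (32.0%), wild-type libraries 2, 4 and 5 lay between −53.9 and −20.6 and the other 5 between 3.36 and 42.2. The labels give no batch. The comparison is therefore also given against wild-type libraries 1 and 3 alone, called the low-Rpph1 pair, and against wild-type libraries 2, 4 and 5 alone, called the high-Rpph1 set.

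**Figure D1:**
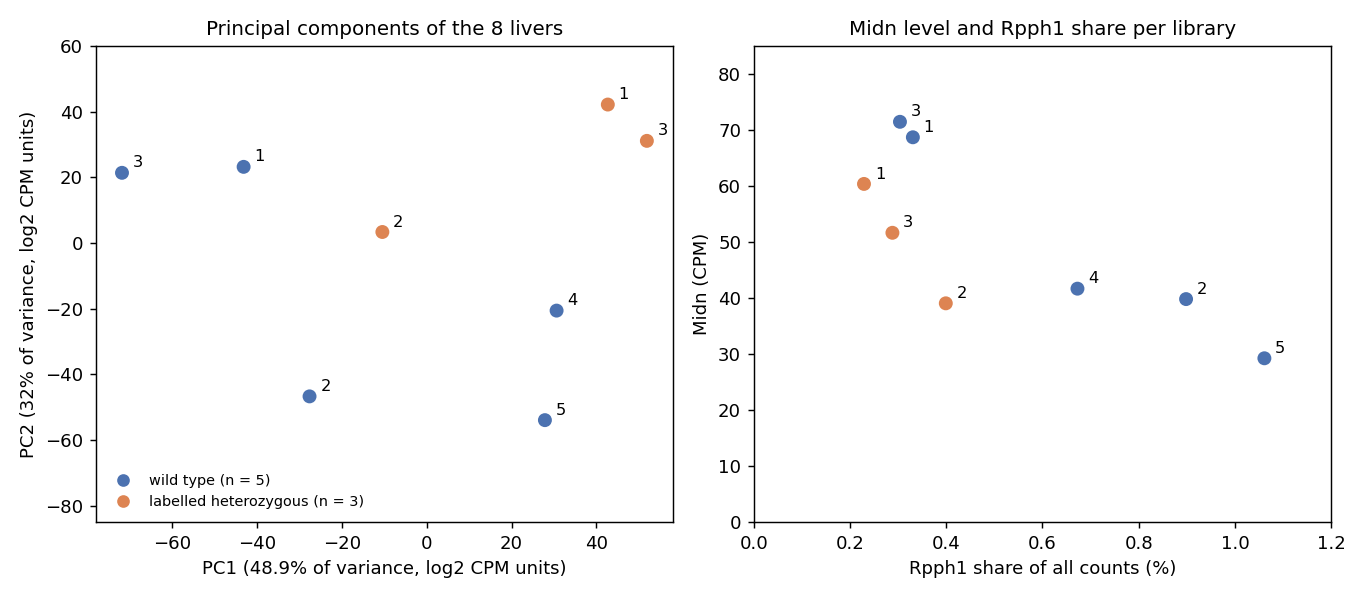
Left, the first and second principal components of log2 CPM (counts scaled to a common library total) for each of the 8 livers; right, Midn CPM against the percentage of counts from Rpph1. Wild-type libraries 2, 4 and 5 sit apart at 0.673 to 1.06% Rpph1, with Midn at 29.3 to 41.7 CPM, and the other 5 libraries have 0.229 to 0.399%.

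Midn itself was measured first, since its level checks the genotype labels. The gene (chromosome 10, 80148272 to 80158368, plus strand, mm10) stood at 50.2 ± 18.8 CPM in wild type (SD, n = 5) and 50.4 ± 10.7 CPM in the het-labelled libraries (SD, n = 3). Wild-type libraries 1 to 5 had 68.7, 39.8, 71.5, 41.7 and 29.3 CPM, and het-labelled libraries 1 to 3 had 60.4, 39.1 and 51.7 CPM. The log2 fold change was 0.00 (SE 0.30; edgeR adjusted p = 0.994) and a two-sided exact permutation test of CPM gave p = 1. Its 95% interval of −0.68 to 0.69 leaves out a loss of 1 on the log2 scale, which is what 1 silent copy of 2 would give. That interval takes all 5 wild-type libraries as 1 group, although their Midn level differed with the Rpph1 share. It therefore does not settle the question for either part of the wild-type libraries alone. In the authors' RPKM values Midn was 13.3 ± 5.30 in wild type and 12.96 ± 2.70 in the het-labelled libraries (SD, n = 5 and n = 3; exact permutation p = 0.929). Against the low-Rpph1 pair, which had a mean of 70.1 CPM, the difference was −0.54 (SE 0.17; edgeR adjusted p = 0.104), and the exact permutation p of 0.2 is the smallest that 10 assignments allow. Against the high-Rpph1 set (36.9 CPM) it was 0.40 (SE 0.19; edgeR adjusted p = 0.167), with an exact permutation p of 0.3 where 0.1 is the smallest possible. The labels do not say which part of the gene was deleted, and counts outside a deleted part check nothing. Midn did not separate the genotypes over all 8 livers, so each direction given from here on is that of the libraries labelled heterozygous relative to wild type.

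Het-labelled livers had more transcript of genes that are typical of male mouse liver and of hepatocytes around the central vein, and less of interferon-response genes and of markers of lipid-laden macrophages, by camera with a preset correlation. Adjusted p was 0.451 for the first 3 lists and 0.543 for the macrophage list with an estimated correlation. Cyp2e1, a pericentral cytochrome P450 that oxidises ethanol, stood at 1977 ± 576 CPM in wild type (SD, n = 5) and 5971 ± 1370.0 CPM in het-labelled libraries (SD, n = 3), a log2 fold change of 1.59 (SE 0.30). Slco1a1, an organic anion transporter of male liver, had 30.5 ± 24.3 and 351 ± 273 CPM. The interferon-induced Ifi44 had 20.5 ± 4.27 and 9.27 ± 1.43 CPM. Fatty acid oxidation, lipid droplet and clock genes also rose as groups by camera with a preset correlation, while chemokine, T and NK cell, matrix and bile duct genes fell. For each of these 7 groups the adjusted p = 0.543 with an estimated correlation. In all, 17 of the 40 gene lists tested rose and 10 fell by limma's camera with a preset correlation of 0.01 (adjusted p under 0.05). The lists were chosen before the data were examined. With an estimated correlation 0 of the 40 lists passed by camera, the smallest adjusted p was 0.451 and 4 had an unadjusted p under 0.05. The estimated correlations ran from 0.05 for insulin signalling to 0.79 for bile duct markers, all above the preset 0.01. Calls at the preset value therefore understate how far members of a list move together. The self-contained limma test fry called 0 lists after adjustment (smallest adjusted p = 0.0835) and 10 at an unadjusted p under 0.05. By list score, the mean over members of log2 CPM centred on the 8 libraries, male-biased, pericentral, interferon-response, clock and endoplasmic reticulum stress genes lay beyond every wild-type value in all 3 het-labelled libraries (exact permutation p = 0.0357 each, the smallest possible, and 0.252 adjusted over the lists). In each other called list at least 1 het-labelled library did not, most often het-labelled library 2. Leaving out wild-type library 3 left 17 lists called, the low-Rpph1 pair alone gave 22, and the high-Rpph1 set alone gave 8.

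**Figure D2:**
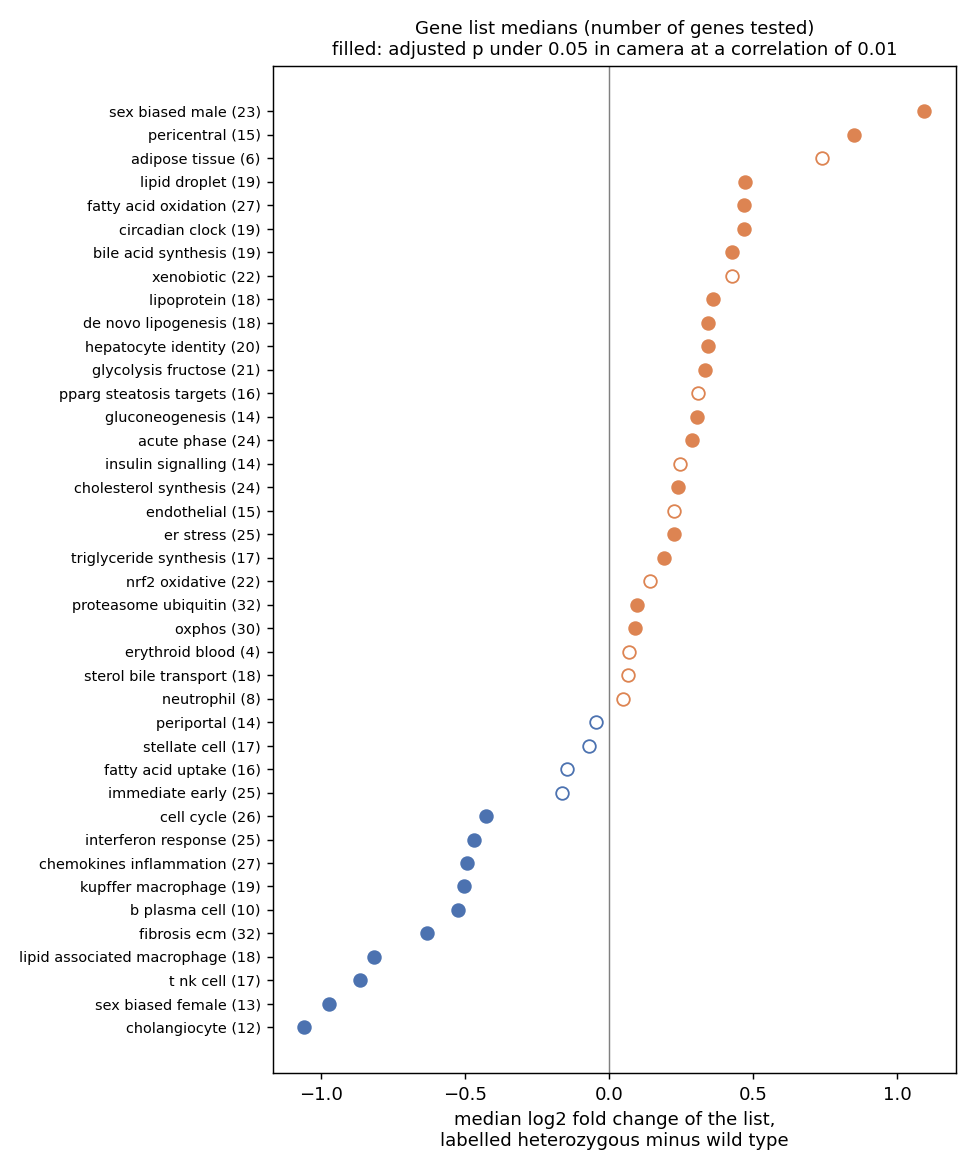
Median log2 fold change (het-labelled relative to wild type) over the tested members of each of the 40 gene lists; filled points have an adjusted p under 0.05 by camera with a preset correlation of 0.01. Male-biased genes lie farthest to the right at 1.10 and bile duct markers farthest to the left at −1.06.

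No single gene passed in edgeR, which called 0 of the 14438 genes tested, while 2271 had an unadjusted p under 0.05 (722 expected by chance), 1487 of them higher and 784 lower. DESeq2 called 176 genes, 100 higher and 76 lower, of which 174 were tested in edgeR and had the same sign there. A limma-voom fit called 0. For 1089 genes every het-labelled library lay above every wild-type one and for 335 below, together 9.86% of genes against 3.57% by chance. Both chance values take no account of genes that move together, so a single split of the libraries can lie far from them. Of the 56 splits into 5 and 3, 7 had an unadjusted count of at least 2271, the real split among them. The 9.86% was not set against the splits. The genes with the smallest edgeR p did not pass the threshold (adjusted p = 0.259 each). On the higher side they were Chrna2, a nicotinic receptor subunit (4.29 ± 0.921 and 11.1 ± 2.67 CPM), Cyp1a2, Hsd3b5, the dehydrogenase gene Dhrs1 (log2 fold change 0.93) and Aarsd1 (0.72). On the lower side were Ifi44, the calcium channel subunit gene Cacna2d4 (−2.37), Enho, which encodes the secreted peptide adropin (4.11 ± 1.13 and 1.37 ± 0.263 CPM), Gucy2c, a guanylate cyclase receptor (−4.58), and the glycosyltransferase gene Galnt3 (−1.37). Gucy2c had 120, 84, 112, 32 and 9 counts in the wild-type libraries and 5, 2 and 1 in the others, and its fold change was −5.30 without het-labelled library 1. DESeq2 gave adjusted p of 4.49e-04 for Chrna2, 4.49e-04 for Enho and 1.49e-04 for Gucy2c. The edgeR count at an unadjusted p under 0.05 was 794 without het-labelled library 1, 877 without het-labelled library 3, 1326 without wild-type library 2 and 3602 without het-labelled library 2. Against the low-Rpph1 pair edgeR called 21 genes, 14 higher and 7 lower, and against the high-Rpph1 set 2632, 1170 higher and 1462 lower. With library size alone as the scaling, 427 genes were higher and 1198 lower at an unadjusted p under 0.05, and the median of all genes was −0.18 instead of 0.00. The split was 1148 higher and 973 lower with RLE scaling, 1333 and 1373 in DESeq2, 1185 and 970 on RPKM with a pseudocount of 0.1, and 1208 and 879 with a pseudocount of 1.

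Genes expressed more in male than in female mouse liver rose as a group, with a median log2 fold change of 1.10 over 23 tested members (camera adjusted p = 1.09e-08; adjusted p = 0.451 with an estimated correlation). Of these, 14 were higher at an unadjusted p under 0.05 and 0 lower, and 12 were higher when adjusted over the list alone. Cyp2d9, a steroid hydroxylase of male liver, had 345 ± 103 CPM in wild type (SD, n = 5) and 1004 ± 376 CPM in het-labelled libraries (SD, n = 3), a log2 fold change of 1.54 (SE 0.32). Elovl3, a fatty acid elongase, had 10.7 ± 6.60 and 55.8 ± 24.7 CPM (2.38, SE 0.50), and Slco1a1 differed by 3.53 (SE 0.72), or 2.69 without het-labelled library 1. Hsd3b5, a steroid reductase of male liver, had 0, 8, 1, 5 and 2 counts in the wild-type libraries and 1715, 73 and 75 in the others. Its log2 fold change was 7.46 (SE 1.27), 4.49 without het-labelled library 1 and 8.07 without wild-type library 2. The list score was above every wild-type value in all 3 het-labelled libraries (exact permutation p = 0.0357, the smallest possible, and 0.252 adjusted over the lists). Female-biased genes fell, with a median of −0.97 over 13 tested members (camera adjusted p = 0.00376; adjusted p = 0.451 with an estimated correlation). Of these, 6 were lower at an unadjusted p under 0.05 and 0 higher, and 2 were lower when adjusted over the list alone. The female-biased score was −0.94 in het-labelled library 1, but in het-labelled libraries 2 (−0.09) and 3 (−0.263) it lay inside the wild-type range of −0.264 to 0.82 (exact permutation p = 0.107). Against the low-Rpph1 pair its difference was −0.31 (95% interval −1.43 to 0.80). Cyp2a4, a steroid hydroxylase of female liver, had 18.0 ± 6.38 and 2.46 ± 2.76 CPM (−2.89, and −4.36 without het-labelled library 2), and the peroxisomal transporter gene Abcd2 had 62.6 ± 11.8 and 25.3 ± 11.4 CPM. Among the genes DESeq2 called, 7 of 22 male-biased genes were higher and 2 of 12 female-biased genes lower (Fisher's exact test over the lists, adjusted p = 7.86e-09 and 0.0234). Fisher's test takes genes as independent, but the estimated correlation was 0.29 in the male-biased, 0.18 in the pericentral and 0.19 in the interferon list. Its p-values here and below may thus be too small. They come from the same libraries as camera and are no separate evidence. In camera the low-Rpph1 pair gave adjusted p of 1.13e-05 for male-biased and 0.0297 for female-biased genes, and the high-Rpph1 set 2.25e-04 and 0.0740. Members such as the Mup, Cyp2d and Cyp2a genes have near-identical copies, so their single values are uncertain. Without the 7 Mup genes the male-biased median was 0.98 over 16 members.

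**Figure D3:**
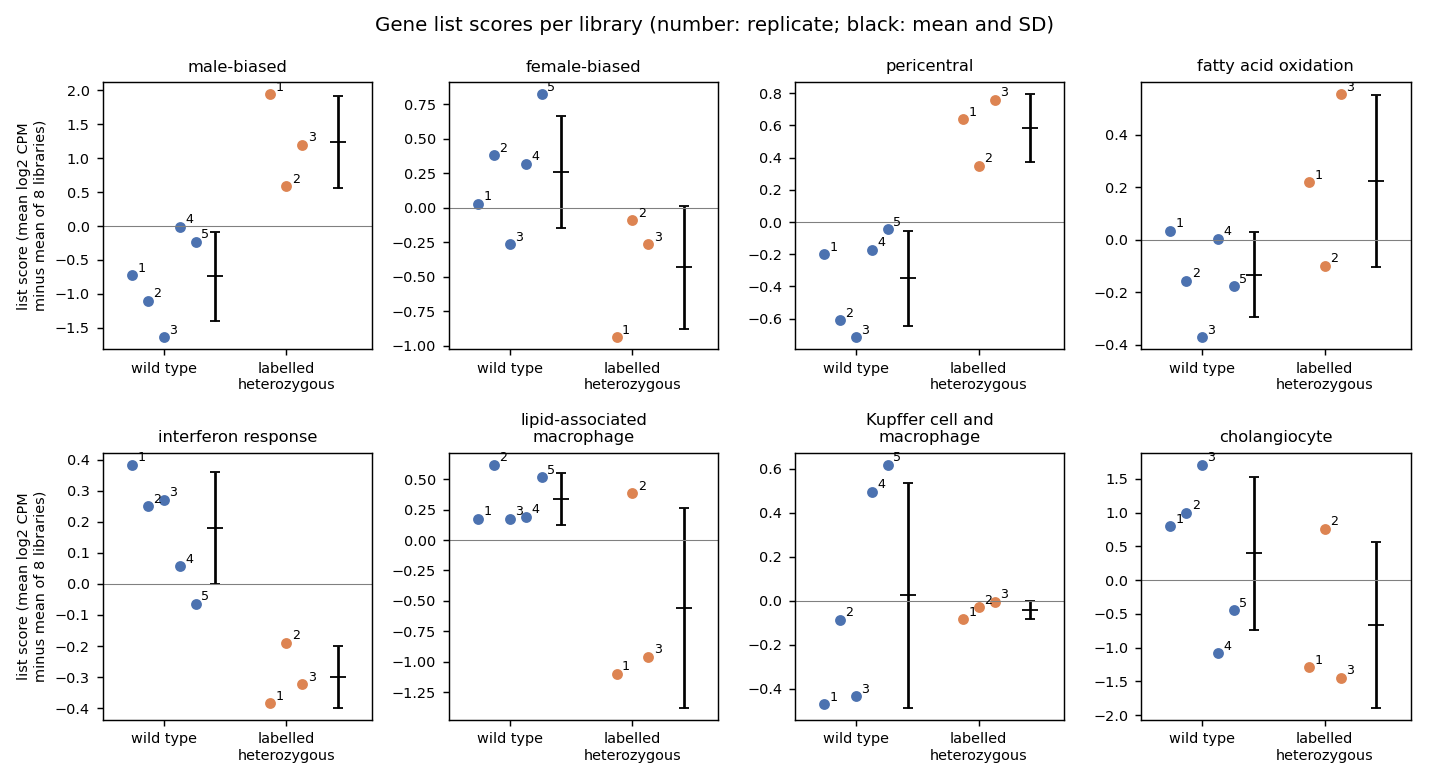
List scores (mean log2 CPM of the members, centred on the 8 libraries) for 8 gene lists, 1 numbered point per liver with the group mean and SD. For male-biased genes wild-type libraries run from −1.64 to −0.02 and het-labelled libraries from 0.58 to 1.94, and for interferon-response genes the groups are likewise apart.

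Pericentral genes, which are expressed by the hepatocytes next to the central vein, rose with a median of 0.85 over 15 tested members (camera adjusted p = 1.15e-05; adjusted p = 0.451 with an estimated correlation). There were 10 members higher at an unadjusted p under 0.05, all 10 also when adjusted over the list alone, and 0 lower. Glul, the glutamine synthetase gene of the innermost pericentral cells, had 524 ± 243 CPM in wild type (SD, n = 5) and 1659.8 ± 289 CPM in het-labelled libraries (SD, n = 3), a log2 fold change of 1.66 (SE 0.39). Cyp1a2, a caffeine-metabolising P450, had 68.7 ± 23.6 and 246 ± 77.8 CPM (1.84, SE 0.31), and the ammonium transporter gene Rhbg had 3.51 ± 0.926 and 9.15 ± 3.81 CPM. DESeq2 called 5 of the 15 higher (Fisher's exact test, adjusted p = 1.66e-06). By camera with the preset correlation the list passed against the low-Rpph1 pair (adjusted p = 2.36e-04) and the high-Rpph1 set (0.00152). These results are not independent, since the het-labelled libraries are the same in both. Periportal genes did not pass (camera adjusted p = 0.939). Their median was −0.05 and their mean 0.19, with 3 higher and 1 lower of 14 at an unadjusted p under 0.05 and 1 higher when adjusted over the list alone, the sulfotransferase gene Sult5a1 at 1.55 ± 1.55 and 11.3 ± 6.08 CPM (2.87, and 3.70 without wild-type library 4). Xenobiotic metabolism genes went both ways, 9 higher and 3 lower of 22 at an unadjusted p under 0.05 and 9 and 2 when adjusted over the list alone (median 0.43, camera adjusted p = 0.145). Among them the bilirubin transferase gene Ugt1a1 had 69.3 ± 19.2 and 155 ± 24.8 CPM, Nr1i3, the nuclear receptor CAR, differed by 1.43 and Cyp2c55 by −2.45. The list passed in camera with library size alone (adjusted p = 0.00478) and without het-labelled library 1 (0.0464) or 2 (0.0455). DESeq2 called 3 members higher and 1 lower (Fisher's exact test, adjusted p = 0.00908 and 0.463).

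**Figure D4:**
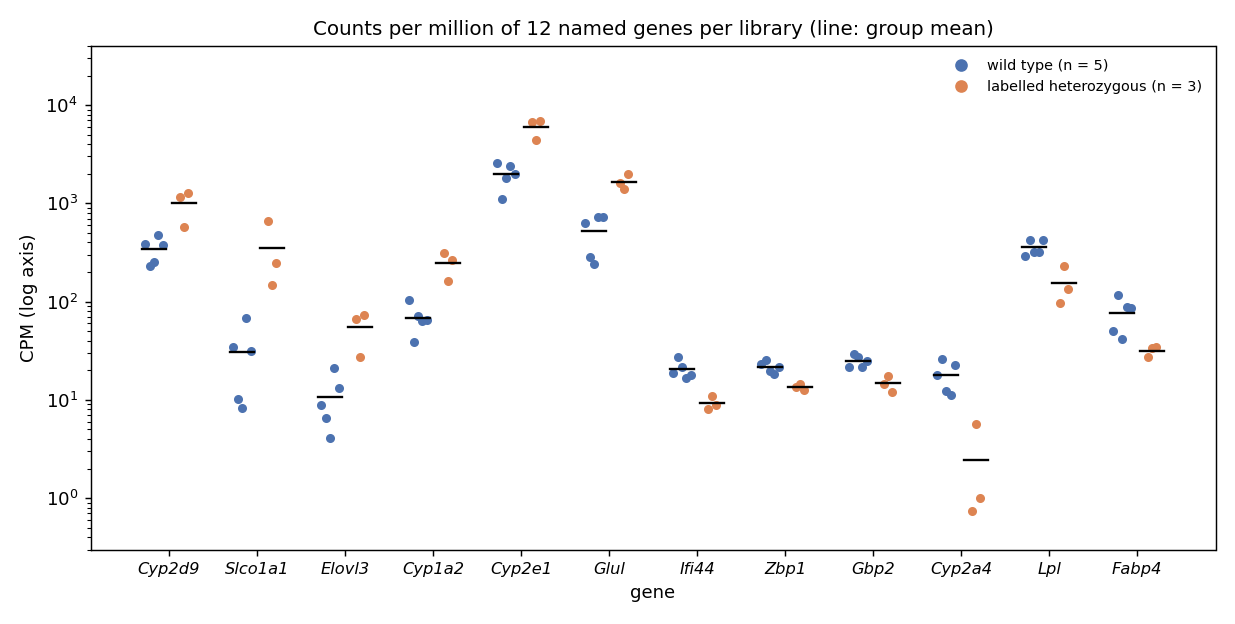
CPM of 12 genes in each of the 8 livers on a log axis, with a line at each group mean. Cyp2e1 runs from 1106 to 2590.2 CPM in wild type and from 4394 to 6862 CPM in het-labelled livers, and Ifi44 from 16.7 to 27.5 CPM and from 8.11 to 10.9 CPM.

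Genes that burn and store fatty acids rose by camera with the preset correlation, and genes that take fatty acids up did not pass. Hepatocyte markers had a median of 0.34 in the same livers, against −1.06 for bile duct, −0.87 for T and NK cell and −0.82 for lipid-associated macrophage markers. For the oxidation, droplet and lipoprotein lists the adjusted p = 0.543 with an estimated correlation. Fatty acid oxidation genes had a median of 0.47, with 15 higher and 1 lower of 27 at an unadjusted p under 0.05 and 8 higher when adjusted over the list alone (camera adjusted p = 1.32e-04; adjusted p = 0.543 with an estimated correlation). Acot1, an acyl-CoA thioesterase induced by PPARα, had 7.82 ± 1.84 CPM in wild type (SD, n = 5) and 17.3 ± 6.31 CPM in het-labelled libraries (SD, n = 3), Slc25a20, the carnitine carrier of mitochondria, had 71.3 ± 10.9 and 119.6 ± 25.0 CPM, and the dehydrogenase gene Acadl differed by 0.49. The oxidation score was 0.22 and 0.55 in het-labelled libraries 1 and 3, but −0.10 in het-labelled library 2, inside the wild-type range of −0.37 to 0.03, and its difference against the low-Rpph1 pair was 0.39 (95% interval −0.518 to 1.305). Lipid droplet genes had the same median of 0.47, with 7 of 19 higher and 6 when adjusted over the list alone (camera adjusted p = 7.81e-04; adjusted p = 0.543 with an estimated correlation). Among them were Lipe, hormone-sensitive lipase (1.17), Fitm2, which helps droplets form (0.82), and Cideb, which loads lipid onto lipoproteins (0.91). Lipoprotein genes had a median of 0.36, with 6 of 18 higher and 0 when adjusted over the list alone (camera adjusted p = 0.00304; adjusted p = 0.543 with an estimated correlation), and the apolipoprotein genes Apoh and Apoa2 differed by 0.82 and 0.91. In het-labelled library 2 the droplet (0.08) and lipoprotein (−0.04) scores also lay inside the wild-type ranges (−0.71 to 0.32 and −0.59 to 0.14). The low-Rpph1 pair gave camera adjusted p of 0.00161 for oxidation, 7.38e-05 for droplets and 0.00102 for lipoproteins, and the high-Rpph1 set 0.0265, 0.206 and 0.206. Fatty acid uptake genes did not pass (median −0.15, camera adjusted p = 0.682), nor did Pparg and its steatosis targets (median 0.31, camera adjusted p = 0.897). Both lists had 3 higher and 3 lower of 16 at an unadjusted p under 0.05 and 2 higher and 2 lower when adjusted over the list alone. Among the genes DESeq2 called, 2 of 15 Pparg targets were higher and 2 lower (Fisher's exact test, adjusted p = 0.0420 and 0.0314), and 2 of 16 uptake genes lower (0.0314) and 1 higher (0.463). Their members included Acsl1, which activates fatty acids (560.0 ± 115 and 1261 ± 381 CPM), the lipoprotein lipase gene Lpl (357 ± 63.9 and 153 ± 68.3 CPM) and the fatty acid binding protein gene Fabp4 (76.8 ± 30.7 and 31.7 ± 3.85 CPM). These genes stand in both lists, and Lpl and Fabp4 are the lower DESeq2 calls of each. The enrichments of the lists are therefore not separate evidence.

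De novo lipogenesis genes rose with a median of 0.34 and 4 of 18 higher at an unadjusted p under 0.05 (camera adjusted p = 0.0130; adjusted p = 0.581 with an estimated correlation). Hepatocyte markers had the same median of 0.34, and a rise of lipogenesis genes apart from theirs was not tested. Mlxipl, a carbohydrate-sensing transcription factor gene, differed by 0.76 and Pklr, the gene of liver pyruvate kinase, by 1.06. Triglyceride synthesis genes rose with a median of 0.19, which was −0.02 with library size alone, and 5 of 17 were higher (camera adjusted p = 0.0292; adjusted p = 0.543 with an estimated correlation). Dgat2, which makes triglyceride from diacylglycerol, differed by 0.74. The lipogenesis score was 0.39 and 0.57 in het-labelled libraries 1 and 3, but −0.15 in het-labelled library 2, next to the wild-type mean of −0.16. The triglyceride score of het-labelled library 2 (0.02) lay inside the wild-type range of −0.32 to 0.10. Neither list had a member past the threshold when adjusted over the list alone. The lipogenesis call was lost without wild-type library 3 (camera adjusted p = 0.106) or het-labelled library 3 (0.155), and the triglyceride call without wild-type library 1 (0.0663) or 3 (0.0619) or het-labelled library 3 (0.0817). The low-Rpph1 pair gave 0.0105 and 0.0351, and the high-Rpph1 set 0.206 and 0.299.

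Bile acid synthesis genes rose with a median of 0.43, 7 of 19 higher at an unadjusted p under 0.05 and 1 when adjusted over the list alone (camera adjusted p = 0.00836; adjusted p = 0.543 with an estimated correlation). Cyp7b1, the oxysterol hydroxylase of the alternative pathway, had 47.0 ± 11.5 CPM in wild type (SD, n = 5) and 119 ± 51.8 CPM in het-labelled libraries (SD, n = 3), and the sterol hydroxylase gene Cyp27a1 differed by 0.69. Cyp7b1 was the only bile acid synthesis gene that DESeq2 called, and it is also a member of the male-biased list. The bile acid synthesis score was 0.51 and 0.39 in het-labelled libraries 1 and 3, but −0.11 in het-labelled library 2, inside the wild-type range of −0.59 to 0.09. Sterol and bile acid transporters did not pass (median 0.06, and −0.09 with library size alone; camera adjusted p = 0.501). Of 18, 3 were higher and 2 lower at an unadjusted p under 0.05, and 2 and 2 when adjusted over the list alone, with the bile acid uptake gene Slc10a1 at 1.31 and the efflux gene Abcc4 at −1.06. Cholesterol synthesis genes rose with a median of 0.24 and 3 of 24 higher (camera adjusted p = 0.0340; adjusted p = 0.588 with an estimated correlation), the sterol dehydrogenase gene Nsdhl at 0.61. Gluconeogenesis genes rose with a median of 0.30 and 6 of 14 higher (camera adjusted p = 0.0372; adjusted p = 0.581 with an estimated correlation), with Foxo1, a transcription factor of fasting, at 0.72. Glycolysis and fructose genes rose with a median of 0.33, 6 higher and 1 lower of 21 (camera adjusted p = 0.0249; adjusted p = 0.543 with an estimated correlation), with the fructose transporter gene Slc2a5 at 1.14. In het-labelled library 2 the cholesterol score (−0.15) lay below the wild-type mean (−0.07) and the gluconeogenesis score (−0.34) below every wild-type value (−0.12 to −0.03), while the glycolysis score (0.07) lay inside the wild-type range of −0.38 to 0.11. None of the last 3 lists had a member past the threshold when adjusted over the list alone. The cholesterol call was lost without wild-type library 3 (camera adjusted p = 0.192) or 4 (0.112) or het-labelled library 1 (0.0550) or 3 (0.220) or with 1 surrogate variable (0.0780), and the glycolysis call without wild-type library 3 (0.0534). The gluconeogenesis call was lost without wild-type library 1 (0.0663) or 3 (0.0619) or het-labelled library 1 (0.324) or 3 (0.0887) or with 1 surrogate variable (0.0507). The low-Rpph1 pair gave 0.00275 for bile acid synthesis, 0.190 for cholesterol synthesis, 0.140 for gluconeogenesis and 0.0396 for glycolysis, and the high-Rpph1 set 0.233, 0.206, 0.206 and 0.205. Hepatocyte markers had a median of 0.34 in the same livers. A rise of these pathways apart from that of hepatocyte markers was not tested. Insulin signalling genes did not pass (median 0.25, 3 higher and 2 lower of 14, 0 when adjusted over the list alone; camera adjusted p = 0.395), with Igfbp2, a growth factor binding protein gene, at −1.04.

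Interferon-response genes fell, with a median of −0.47 and 13 of 25 members lower at an unadjusted p under 0.05, 0 higher, and 8 lower when adjusted over the list alone (camera adjusted p = 1.09e-08; adjusted p = 0.451 with an estimated correlation). Ifi44 differed by −1.15 (SE 0.20) and the antiviral gene Mx1 by −1.06. Zbp1, a sensor of viral nucleic acid, had 21.8 ± 2.95 CPM in wild type (SD, n = 5) and 13.6 ± 0.900 CPM in het-labelled libraries (SD, n = 3), and the GTPase gene Gbp2 had 24.9 ± 3.47 and 14.7 ± 2.83 CPM. The list score was below every wild-type value in all 3 het-labelled libraries (exact permutation p = 0.0357, the smallest possible, and 0.252 adjusted over the lists), and DESeq2 called 5 of 25 lower (Fisher's exact test, adjusted p = 4.67e-06). Camera gave an adjusted p of 5.57e-09 for the low-Rpph1 pair and 0.00624 for the high-Rpph1 set. Markers of lipid-associated macrophages, the macrophages that gather in fatty liver, fell with a median of −0.82 and all 18 fold changes negative (camera adjusted p = 1.09e-08; adjusted p = 0.543 with an estimated correlation). Of these 4 were lower at an unadjusted p under 0.05 and 1 when adjusted over the list alone, with Lpl at −1.22, the proton pump gene Atp6v0d2 at −0.86 and the endosomal marker Cd63 at −0.96. Cd63 was at −1.79 without het-labelled library 2, with 18.7, 64.4 and 19.9 CPM in het-labelled libraries 1, 2 and 3. The list score was −1.10 and −0.96 in het-labelled libraries 1 and 3 but 0.39 in het-labelled library 2, inside the wild-type range of 0.17 to 0.62. The score difference was −0.89 (exact permutation p = 0.143, and 0.272 adjusted over the lists), and −1.36 without het-labelled library 2. Against the low-Rpph1 pair it was −0.73 (95% interval −2.67 to 1.21). The low-Rpph1 pair gave a camera adjusted p of 0.00554 and the high-Rpph1 set 2.25e-04. Chemokine and inflammation genes fell with a median of −0.50, 8 of 27 lower and 0 when adjusted over the list alone (camera adjusted p = 4.29e-05; adjusted p = 0.543 with an estimated correlation). Among them were the monocyte-attracting Ccl8 (−2.30, and −3.08 without het-labelled library 2, on 3, 6 and 1 counts in the het-labelled libraries), the adhesion molecule gene Vcam1 (144 ± 31.4 and 83.5 ± 15.6 CPM) and Cxcl16 (−0.91). The chemokine score of het-labelled library 2 (0.09) lay within the wild-type range. This list had a camera adjusted p of 0.0610 against the low-Rpph1 pair and 7.75e-04 against the high-Rpph1 set.

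T and NK cell markers fell with a median of −0.87, 4 of 17 lower at an unadjusted p under 0.05 and 0 when adjusted over the list alone (camera adjusted p = 2.74e-04; adjusted p = 0.543 with an estimated correlation). The NK receptor genes Klrd1 and Ncr1 differed by −1.53 and −1.43, and Klrd1 by −2.23 without het-labelled library 2. The T and NK cell score was −0.80 and −0.75 in het-labelled libraries 1 and 3, but 0.10 in het-labelled library 2, inside the wild-type range of −0.53 to 0.81. With the low-Rpph1 pair the camera adjusted p was 3.75e-05 and with the high-Rpph1 set 0.212. B and plasma cell markers fell with a median of −0.52, 1 of 10 lower and 0 when adjusted over the list alone (camera adjusted p = 0.0292; adjusted p = 0.543 with an estimated correlation), and Ms4a1, which encodes CD20, differed by −1.13. The B and plasma cell score of het-labelled library 3 (−0.04) lay inside the wild-type range of −0.14 to 0.56. This call was lost without wild-type library 3 (0.126) or het-labelled library 1 (0.0945), with library size alone (0.140), with 1 surrogate variable (0.0523), and against the high-Rpph1 set (0.305). Kupffer and general macrophage markers fell by camera (adjusted p = 0.00811; adjusted p = 0.543 with an estimated correlation), with a median of −0.50, a mean of −0.14, 2 higher and 7 lower of 19, and 0 past the threshold when adjusted over the list alone. The complement gene C1qa had 119.7 ± 27.1 CPM in wild type (SD, n = 5) and 69.5 ± 19.0 CPM in het-labelled libraries (SD, n = 3), and the phagocyte gene Mpeg1 differed by −0.66. The Kupffer score lay inside the wild-type range in all 3 het-labelled libraries. Against the low-Rpph1 pair the Kupffer list did not pass (camera adjusted p = 0.839), and its score was higher by 0.41 (95% interval 0.31 to 0.52) in het-labelled libraries. Against the high-Rpph1 set the score difference was −0.38 (camera adjusted p = 0.0166). Neutrophil markers did not pass (median 0.05, and −0.11 with library size alone, mean −0.04; 0 of 8 at an unadjusted p under 0.05; camera adjusted p = 0.910).

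Extracellular matrix and fibrosis genes fell with a median of −0.63 and 28 of 32 fold changes negative (camera adjusted p = 4.54e-04; adjusted p = 0.543 with an estimated correlation). Only 2 were lower and 1 higher at an unadjusted p under 0.05, and 0 passed when adjusted over the list alone. Thbs2, a matrix glycoprotein gene, differed by −1.25 and the fibrillar collagen gene Col5a2 by −1.18, against 0.88 for Col5a3 and 0.81 for Fn1, the fibronectin gene that hepatocytes also express. The matrix score was −0.48 and −0.86 in het-labelled libraries 1 and 3, but 0.36 in het-labelled library 2, above wild-type libraries 2, 4 and 5 (0.15, −0.20 and −0.41). Bile duct markers fell with a median of −1.06 and all 12 fold changes negative, although 0 of the 12 had an unadjusted p under 0.05 (camera adjusted p = 0.00254; adjusted p = 0.543 with an estimated correlation). Cftr, the chloride channel of the duct lining, had 10.1 ± 8.05 CPM in wild type (SD, n = 5) and 2.77 ± 3.34 CPM in het-labelled libraries (SD, n = 3), a log2 fold change of −1.89, or −3.57 without het-labelled library 2. The bile duct score had the widest spread among wild-type livers of the 40 lists, 6.91-fold between wild-type libraries 4 and 3, and het-labelled library 2 (0.76) lay within their range. In camera the low-Rpph1 pair gave adjusted p of 1.56e-06 for matrix genes and 7.38e-05 for bile duct markers, and the high-Rpph1 set 0.601 and 0.509. The low-Rpph1 pair also lay lowest on the first principal component, so its smaller p-values cannot be told apart from that structure. Cell cycle genes fell with a median of −0.43, 2 of 26 lower and 0 when adjusted over the list alone (camera adjusted p = 2.92e-04; adjusted p = 0.543 with an estimated correlation). The mitotic kinase gene Cdk1 differed by −0.97 and the topoisomerase gene Top2a by −0.68. Without het-labelled library 2 these were −1.57 and −1.27, and without het-labelled library 1 −0.63 and −0.45. The cell cycle score was −0.68 and −0.54 in het-labelled libraries 1 and 3, but 0.44 in het-labelled library 2, above every wild-type value (0.02 to 0.31). The list had an adjusted p of 0.00984 in camera against the low-Rpph1 pair and 0.0533 against the high-Rpph1 set. Stellate cell markers (median −0.07, 2 higher of 17; camera adjusted p = 0.501) and endothelial markers (0.23, 1 higher of 15; camera adjusted p = 0.145) did not pass, with 0 members past the threshold when adjusted over the list alone. The endothelial list passed in camera without het-labelled library 2 (adjusted p = 0.0349).

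Hepatocyte identity genes rose with a median of 0.34, 6 of 20 higher and 0 when adjusted over the list alone (camera adjusted p = 0.00474; adjusted p = 0.543 with an estimated correlation). Ttr, the gene of the plasma carrier transthyretin, had 1410.4 ± 294 CPM in wild type (SD, n = 5) and 2534 ± 494 CPM in het-labelled libraries (SD, n = 3). The hepatocyte score was 0.42 and 0.30 in het-labelled libraries 1 and 3, but −0.07 in het-labelled library 2, inside the wild-type range of −0.33 to 0.04. Clock genes rose with a median of 0.47, 7 of 19 higher and 5 when adjusted over the list alone (camera adjusted p = 7.81e-04; adjusted p = 0.543 with an estimated correlation). Hlf, a transcription factor of clock output, had 50.2 ± 10.3 and 99.0 ± 20.6 CPM, and the repressor gene Cry1 differed by 0.90. Time of collection was not among the sample values used here, so its part in the clock result was not tested. The low-Rpph1 pair gave camera adjusted p of 0.00847 for hepatocyte genes and 0.0717 for clock genes, and the high-Rpph1 set 0.206 and 0.00671. Endoplasmic reticulum stress genes rose with a median of 0.23, 7 of 25 higher and 3 when adjusted over the list alone (camera adjusted p = 0.0153; adjusted p = 0.543 with an estimated correlation), and the disulfide isomerase genes Pdia4 and Pdia6 differed by 0.64 and 0.59. Acute-phase genes rose with a median of 0.29 and 3 of 24 higher (camera adjusted p = 0.0432; adjusted p = 0.550 with an estimated correlation), with the lipopolysaccharide-binding Lbp at 0.68. The acute-phase scores of het-labelled libraries 2 and 3 (both 0.12) lay inside the wild-type range of −0.57 to 0.26. The stress call was lost without wild-type library 3 (0.0619) or het-labelled library 3 (0.0653), and the acute-phase call without wild-type library 1 (0.0772) or 3 (0.209) or het-labelled library 1 (0.0917) or 2 (0.0850), with a mean of at least 1 CPM (0.0561) or with 1 surrogate variable (0.0665). Camera on the low-Rpph1 pair gave 0.0284 for stress and 0.00554 for acute-phase genes, and the high-Rpph1 set 0.206 and 0.566.

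Proteasome genes, of interest because midnolin works with the proteasome, rose with a median of 0.10, which was −0.07 with library size alone, and 7 of 32 were higher at an unadjusted p under 0.05 (camera adjusted p = 0.0406; adjusted p = 0.588 with an estimated correlation). Psmc4, an ATPase of the regulatory particle, differed by 0.61. Oxidative phosphorylation genes rose with a median of 0.09, which was −0.03 with library size alone, and 6 of 30 were higher (camera adjusted p = 0.0402; adjusted p = 0.715 with an estimated correlation). Acute-phase, proteasome and oxidative phosphorylation lists each had 0 members past the threshold when adjusted over the list alone. The proteasome and oxidative phosphorylation scores of all 3 het-labelled libraries lay inside the wild-type ranges. Proteasome genes no longer passed in camera without wild-type library 1 (adjusted p = 0.138) or 3 (0.604) or het-labelled library 3 (0.193), nor did oxidative phosphorylation genes (0.285, 0.775 and 0.184). The proteasome call was also lost with library size alone (0.194), a mean of at least 1 CPM (0.0567) and 1 surrogate variable (0.409), and the oxidative phosphorylation call with 1 surrogate variable (0.308). Both lists rose against the low-Rpph1 pair (2.31e-06 and 6.40e-10), while against the high-Rpph1 set their camera direction was down without passing (0.571 and 0.206). Oxidative stress genes driven by NRF2 did not pass (median 0.14, and −0.09 with library size alone, mean −0.04; 5 higher and 1 lower of 22; camera adjusted p = 0.504), with the catalase gene Cat at 0.77. Immediate early genes, among which reported substrates of midnolin lie, did not pass either (median −0.16, 3 higher and 2 lower of 25; camera adjusted p = 0.286), with Zfp36, an mRNA-decay factor gene, at 0.84. Only transcripts were measured, so the protein level of those substrates is not addressed. In both lists 0 members passed when adjusted over the list alone. Against the low-Rpph1 pair the 95% interval of the score difference left out 0 for male-biased, pericentral, interferon-response, T and NK cell, droplet, triglyceride, acute-phase, proteasome and oxidative phosphorylation genes, and for Kupffer markers in the direction opposite to their call. It held 0 for the other called lists. These intervals rest on 2 wild-type libraries, and with 10 assignments an exact permutation p cannot fall below 0.2.

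Markers of other tissues were low or mixed. Of 12 adipose tissue genes 6 were tested, and 3 were higher and 1 lower, both at an unadjusted p under 0.05 and when adjusted over the list alone (median 0.74, camera adjusted p = 0.118). The adipokine gene Cfd had 1.64 ± 1.23 CPM in wild type (SD, n = 5) and 39.6, 1.94 and 20.1 CPM in het-labelled libraries 1, 2 and 3, a log2 fold change of 3.67 that was 2.77 without het-labelled library 1. Fabp4 differed by −1.28. The adipose list passed in camera without het-labelled library 2 (adjusted p = 0.0165) and with library size alone (0.0143). DESeq2 called 2 of the 6 higher and 1 lower (Fisher's exact test, adjusted p = 0.0112 and 0.208). Red cell and platelet genes did not pass (median 0.07, and −0.12 with library size alone; 1 higher and 1 lower of 4, 1 higher when adjusted over the list alone; camera adjusted p = 0.910), with Alas2, the haem synthesis gene of red cells, at 0.88. Muscle (3 members) and exocrine pancreas (1 member) had too few tested genes for a list test, and 0 of them had an unadjusted p under 0.05.

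For 22 genes of steatosis, fibrosis and inflammation named in advance, 12 fold changes were positive and 10 negative. In edgeR 0 of them passed over all genes or when adjusted over the list alone, and 1 had an unadjusted p under 0.05. That gene was Plin4, a lipid droplet coat protein gene, at 70.4 ± 28.7 CPM in wild type (SD, n = 5) and 128.9 ± 36.7 CPM in het-labelled libraries (SD, n = 3), a log2 fold change of 0.87 (edgeR adjusted p = 0.273). Pparg, the lipogenic nuclear receptor gene, had 23.2 ± 1.82 and 26.7 ± 8.46 CPM, the fatty acid synthase gene Fasn 516 ± 168 and 524 ± 179 CPM, and Cd36, a fatty acid receptor gene, 755 ± 434 and 488 ± 137 CPM. Without het-labelled library 3 the log2 fold changes of Pparg (0.20) and Fasn (0.02) were −0.01 and −0.29. The collagen gene Col1a1 differed by −0.40 (SE 0.70), 0.01 without wild-type library 3 and −0.89 without het-labelled library 2. Trem2, a receptor of lipid-associated macrophages, had 23.9 ± 5.04 and 13.5 ± 10.98 CPM. Its log2 fold change of −0.83 was −1.73 without het-labelled library 2, −0.48 without het-labelled library 1 and −0.56 without het-labelled library 3.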

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

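No tests in this part were chosen after the result was seen. A library stood apart from the other 4 wild-type libraries in 2 of 81 measures examined, where chance gives about 1 in 20. Chrna2, a nicotinic receptor subunit gene, had 5.88 CPM in wild-type library 4 against 3.67 to 4.31 CPM in the other wild-type libraries. Enho, the adropin gene, had 6.13 CPM in wild-type library 2 against 3.51 to 3.73 CPM.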

How the results depend on the processing

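The fits without wild-type libraries 1 and 3, without wild-type libraries 2, 4 and 5, and without Rn45s and Rpph1 were chosen after the data were seen. The count of 0 genes past the threshold in edgeR (2271 unadjusted) was also 0 with RLE scaling, library size alone, limma-voom, both RPKM fits, both filters, no robust estimation, every other threshold and each library left out. DESeq2 called 176 and the fit with 1 surrogate variable 3, with 4774 unadjusted. Those 3 genes, named after their values were seen, were Dkk4 (log2 fold change 3.48), Mup14 (3.08) and Nat8 (1.33; edgeR adjusted p = 0.0429). Without wild-type libraries 1 and 3 there were 2632 genes and 5228 unadjusted, and without wild-type libraries 2, 4 and 5 there were 21 and 4630. With 1 library left out the unadjusted count ran from 794 to 3602. Without Rn45s and Rpph1 it stayed at 2271. The log2 fold change of Midn ran from −0.14 to 0.17 with 1 library left out and was −0.26 with library size alone. The count of called lists, 27, ran from 17 to 29 with 1 library left out. It was 27 with ranks or library size alone, 25 of 39 with the stricter filter, 21 with the surrogate variable, 0 with an estimated correlation, 0 in fry, 8 without wild-type libraries 1 and 3 and 22 without wild-type libraries 2, 4 and 5. In 17 of the 27 lists the call held with each library left out, and 0 called lists reversed there. Without wild-type libraries 1 and 3 the camera direction of proteasome (adjusted p = 0.571) and oxidative phosphorylation genes (0.206) turned to down without passing. Of 182 named genes 22 changed sign in some setting, in 61 of 3824 values, and 39 passed in DESeq2. The cause of these differences was not tested. No paired analysis was possible because replicate numbers were given in accession order only.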

Other observations

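The tests on the split of the wild-type libraries by Rpph1 share, on scaling and on the share of non-hepatocyte cells were chosen only after the result was seen; the other tests were fixed earlier. Of 19 bile acid synthesis genes 15 had a positive and 4 a negative fold change, with 7 higher and 0 lower at an unadjusted p under 0.05 in edgeR. Cyp8b1, the 12α-hydroxylase that sets the makeup of the bile acid pool, had 49.9 ± 25.8 CPM in wild type (SD, n = 5) and 252, 28.7 and 234 CPM in het-labelled libraries 1, 2 and 3. Cyp7a1, the rate-limiting enzyme of the main pathway, had 678 ± 240.2 and 545 ± 216 CPM (SD, n = 5 and n = 3). Among other P450 genes, Cyp2c54 had 18.2 ± 8.70 and 126 ± 94.5 CPM (log2 fold change 2.79; DESeq2 adjusted p = 0.00265), the steroid 17α-hydroxylase gene Cyp17a1 23.7 ± 12.6 and 9.94 ± 3.05 CPM, and Cyp2b10, a target of the receptor CAR, 4.26 ± 2.98 and 0.915 ± 1.11 CPM (−2.21, and −3.92 without het-labelled library 3). In edgeR the adjusted p of these 5 genes lay between 0.259 and 0.641.

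Of the 56 splits of the 8 libraries into 5 and 3, all 56 match the real edgeR count of 0 by definition, so that comparison decides nothing; the highest other count was 3272. Chance cannot be excluded for the other counts between genotypes. For the unadjusted count 7 splits were as large (real 2271, highest other 5394), for DESeq2 on the 14438 genes 9 (real 191, highest other 4421), and for called lists 4 (real 27, highest other 29). The highest gene counts all came from setting wild-type libraries 2, 4 and 5 against the rest, which points to a structure of the samples that follows the Rpph1 share. Against the 2 wild-type libraries of low share edgeR called 21 genes and against the other 3 it called 2632. The labels name no batch, and no biological explanation of that structure was tested.

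Male-biased genes were higher in het-labelled livers by 1.98 in list score, with wild-type livers themselves spanning 3.08-fold. A single library as the carrier is argued against by a difference of at least 1.63 with any library left out, the lowest being without het-labelled library 1. Scaling is argued against by the list median itself, 1.10 with TMM and at lowest 0.98 with library size alone, RLE or DESeq2, while library size alone moved the median of all genes to −0.18; the test fixed earlier, the list median relative to all genes (1.17 with library size alone), decides nothing because scaling moves genes alike. Against the wild-type pair of low Rpph1 share the difference was 2.42 (95% interval 0.483 to 4.36), which argues against the Rpph1 share as its carrier. That rests on 2 wild-type libraries, and the exact permutation p of 0.2 is the smallest that 10 assignments allow. The pair also lay lowest on the first principal component. Wild-type scores were −0.73, −1.11 and −1.64 in libraries 1, 2 and 3, against −0.02 and −0.23 in libraries 4 and 5. Sample structure along that component is therefore not excluded. As a hypothesis, the Midn genotype may affect the programme of male-typical liver genes, but Midn transcript itself did not separate the genotypes, chance is not excluded for the counts above, and differences in hormone state between livers were not tested.

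Interferon-response genes were lower by 0.479 in list score, and the difference stayed at −0.43 or beyond with any library left out, the closest to 0 being without wild-type library 1. Against the wild-type pair of low Rpph1 share it was −0.63 (95% interval −0.897 to −0.356). The exact permutation p there was 0.2, the smallest that 10 assignments allow. An equal fall of all non-hepatocytes is argued against by endothelial markers, whose score difference was 0.13. It lay 0.61 above that of interferon genes (95% interval 0.317 to 0.896; exact permutation p = 0.0357, the smallest possible). The interferon score alone already had that permutation p, so the contrast adds little. Stellate markers were not set against interferon genes in this way. Score differences were −0.11 for stellate, −0.53 for matrix and −1.05 for bile duct genes. Score differences of immune markers were −0.89 for lipid-associated macrophages, −0.77 for T and NK cells, −0.40 for B and plasma cells, −0.06 for Kupffer cells (0.41 against the pair of low share) and −0.01 for neutrophils. A lower share of some non-hepatocytes, such as lymphocytes or lipid-associated macrophages, stays open and may account for the difference. So may a lower response per cell, and chance is not excluded.

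Markers of lipid-associated macrophages were lower by 0.892 in list score (exact permutation p = 0.143). The difference was −0.62 without het-labelled library 1 and −1.36 without het-labelled library 2, so that a single library did not carry it. It lay in het-labelled libraries 1 and 3, since het-labelled library 2 (0.39) was inside the wild-type range of 0.17 to 0.62. The Rpph1 structure cannot be told apart from genotype here, since the difference against the wild-type pair of low share was −0.73 with a 95% interval of −2.67 to 1.21. Fewer macrophages of every kind cannot be told apart either, since Kupffer markers lay 0.83 above (95% interval −0.256 to 1.91; exact permutation p = 0.107). A smaller pool of these cells in het-labelled livers 1 and 3 may account for the difference, and counting cells in tissue sections would test it.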
